A study of Rattus rattus with 8 samples.

How the data were processed

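Messenger RNA of 8 samples of sorted neonatal rat cardiomyocyte cultures was sequenced, 4 from 2n and 4 from 4n cells. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 to the rat build Rnor 6.0, which is of Rattus norvegicus, and the labels give the strain as SD although they name the organism as Rattus rattus. The counting tool, its filters and its strand setting are not given in the sources used here. The deposited table holds, per the file headers, a count and an FPKM value for each of 30957 Ensembl rat genes and each library. The deposited counts are whole numbers, not normalized. The deposited FPKM values equal the counts divided by a constant per gene and by the library's total count over the table, which includes the mitochondrial genes. Gene names and coordinates are those of the table.

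A few genes of the fixed lists that are abundant in many cells were listed at 0 in all 8 libraries, among them Col1a2 and Myh9, so a value of 0 in this table can come from the counting. Without a stated strand setting, reads of a gene and of a partner on the opposite strand cannot be told apart.

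Groups and replicate numbers were taken from the sample titles. Because the groups share replicate numbers and the descriptions of libraries with the same number begin with the same code, it was checked, before calls were compared, whether the numbers pair the samples. The deviations of log2 CPM from the group means correlated within the pairs at 0.43, 0.58, 0.27 and 0.65 for replicates 1 to 4, and each library correlated best with its own number, so the numbers were taken to pair the samples. The pairing therefore comes from the data and the descriptions, not from a stated protocol. The libraries of a group differed from each other by more than sampling noise, with a chi-square per degree of freedom between 36.4 and 75.3 among 2n and between 58.6 and 421 among 4n libraries, so none was counted as a repeat of another.

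Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (12983 genes), libraries scaled by TMM, and a quasi-likelihood model with robust dispersion fitted with the group as its factor. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method over all genes tested, and the threshold was 0.05. Standard errors were taken from the fold change and the F statistic. The same model with the replicate number as a block was an alternative set in advance. CPM values use the TMM-scaled library sizes, and log2 CPM values a prior count of 2. With 14783521 to 21033772 counts per library, 1 CPM is at least 14.8 counts before scaling.

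The 19 gene lists and 8 lists of cell type markers, the tests and the alternatives were fixed before the data were examined, except where stated. Spellings of 2 mitochondrial symbols were matched to the table afterwards. Lists with at least 3 tested members, 26 in all, were tested with camera (limma 3.58.1, preset correlation of 0.01) and adjusted over the 26 lists, with an estimated correlation and fry beside it, also, as added after seeing the results, for lists called only under an alternative. With the estimated correlation 0 lists were called, the smallest adjusted p being 0.378, with 3 lists at an unadjusted p under 0.05. With fry 4 were called, all higher in 4n: the sarcomere, cardiomyocyte, calcium handling and fetal lists. With the replicate block none of these 4 passed with fry (adjusted p from 0.0794 to 0.0899). The smallest adjusted p with the block and the estimated correlation was 0.532. With camera's preset correlation, 21 of all 35 splits of the 8 libraries, the real one included, called 12 or more lists. A call by it alone is therefore weak evidence. Shares of counts were compared by exact two-sided permutation tests of 4 against 4 libraries, whose smallest p is 0.0286, and pairs by sign flips, whose smallest p is 0.125.

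Named genes follow a rule in 3 parts. The first takes the 10 genes per direction with the largest fold among those past the threshold with a symbol, at least 5 CPM in a group and the same sign in at least 3 pairs. Where too few pass, the genes with the smallest unadjusted p follow and are said not to pass. The next takes up to 4 members with the smallest unadjusted p of each list that was called or has 3 or more members past the threshold. The last is a fixed set of 15 genes of the cell cycle, hypoxia and heart muscle. A few genes that the rule selects are not reported here.

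The test was checked on simulated counts of 4n against 2n libraries over 12925 genes. Both libraries of a pair were given the same level, and the noise followed the fit with the block. The common dispersion of that fit was 0.0306, against 0.0790 without the block. The wider spread of the real 4n libraries was therefore not simulated, and the least abundant genes were not among those changed. Without the block, 37% of genes changed 2-fold and 79% of genes changed 4-fold were recovered, with 1 false among 117 calls. With the block these were 79% and 99%, with 13 false among 191 calls, which is over the 5% aimed at.

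The alternatives were the block, DESeq2 size factors, upper-quartile and total count scaling, no filter or a mean of at least 10 CPM, DESeq2 1.42.0 with and without the block, limma-voom, a dispersion that is not robust, a minimum of 2-fold, genes with symbols only, the FPKM values with limma-trend on log2(FPKM + 1) with at least 1 FPKM in 4 libraries, and leaving out each library or each pair. Scaling on the counts without the mitochondrial genes was added after seeing the data. The settings planned for a table without counts were not needed. Figures were drawn with matplotlib from these results.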

Results

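RNA sequencing was used to compare diploid (2n) with tetraploid (4n) cells sorted from cultures of neonatal rat cardiomyocytes, heart muscle cells isolated from pups 1 to 3 days after birth. The cells had been enriched by differential adherence, in which fibroblasts stick to the dish sooner than cardiomyocytes, and cultured for 24 h with 0.2 mM AraC, an inhibitor of DNA synthesis. They were then serum-starved and held at 1% oxygen for 48 h, a treatment given to induce polyploid, multinucleated cells. Sorting was by DNA content, read from the DNA dye Hoechst at 2 µg/mL. A cell with a 4n signal in such a sort can have a tetraploid nucleus, be binucleated or be in the G2 or M phase of the cell cycle. A pair of 2n cells that pass the sorter stuck together also reads as 4n, and the labels do not separate these. There were 8 libraries, 4 per group, described as coming from independent experiments, and all came from hypoxic cultures. The comparison asks which transcripts differ between the 4n and the 2n cells.

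Total gene counts lay between 14783521 and 21033772 per library. In the 2n group, replicates 1 to 4 had 14783521, 21033772, 17637567 and 19657990 counts. In the 4n group they had 16727259, 15551188, 16885512 and 15326219. Of 30957 genes in the table, 12983 had enough counts to be tested.

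Shares of counts taken by cardiomyocyte, mitochondrial and matrix genes are given as values, since none of 8 shares compared passed after adjustment (smallest adjusted p = 0.0762, exact two-sided permutation test). The 11 cardiomyocyte markers found in the table took 0.0786% ± 0.0197 of the counts in 2n and 1.14% ± 0.900 in 4n (SD, n = 4 each). This share was higher in 4n in 4 of 4 pairs of libraries with the same replicate number. Without pairing, an exact two-sided permutation test gave p = 0.0286, the smallest it allows here, and an adjusted p = 0.0762 over 8 shares. The 4n values were 0.400%, 0.654%, 2.42% and 1.08% for replicates 1 to 4, so the 4n libraries differed from each other by more than the 2n libraries did. Genes of the mitochondrial chromosome took between 2.87% and 3.82% of the counts in the 2n libraries. In 4n replicates 2, 3 and 4 they took 25.0%, 25.9% and 24.1%, and in 4n replicate 1 they took 3.71%, within the 2n range (exact two-sided permutation test, p = 0.0571, adjusted p = 0.0762). Genes of the extracellular matrix took 14.0% ± 0.686 in 2n and 9.19% ± 3.40 in 4n (SD, n = 4 each), lower in 4n in 4 of 4 pairs (exact two-sided permutation test, p = 0.0571, adjusted p = 0.0762). The matrix share of 4n replicate 1 was 13.6%, within the 2n range of 13.3% to 14.9%. The shares are of all counts, so the larger mitochondrial share of 4n replicates 2, 3 and 4 lowers their matrix share too. Part of the matrix difference therefore comes from the mitochondrial counts. With the mitochondrial genes left out, the median log2 fold change of the matrix list was -0.47. An exact two-sided permutation test by sign flips within pairs gave p = 0.125 for the cardiomyocyte, mitochondrial and matrix shares. That is the smallest p that 4 pairs allow, so with pairing no share could pass. The collagen gene Col1a1 stood at 28183 ± 3310 CPM, or counts scaled to library size, in 2n and 22931 ± 7353 in 4n, against 177 ± 76.0 and 4048 ± 3569 CPM for Actc1, the cardiac actin gene (SD, n = 4 each). In a principal component analysis of log2 CPM, the first component held 52.7% of the variance and placed the 2n libraries between -47.53 and -24.36. The 4n libraries lay at -1.94, 20.73, 78.65 and 51.40 for replicates 1 to 4.

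**Figure D1:**
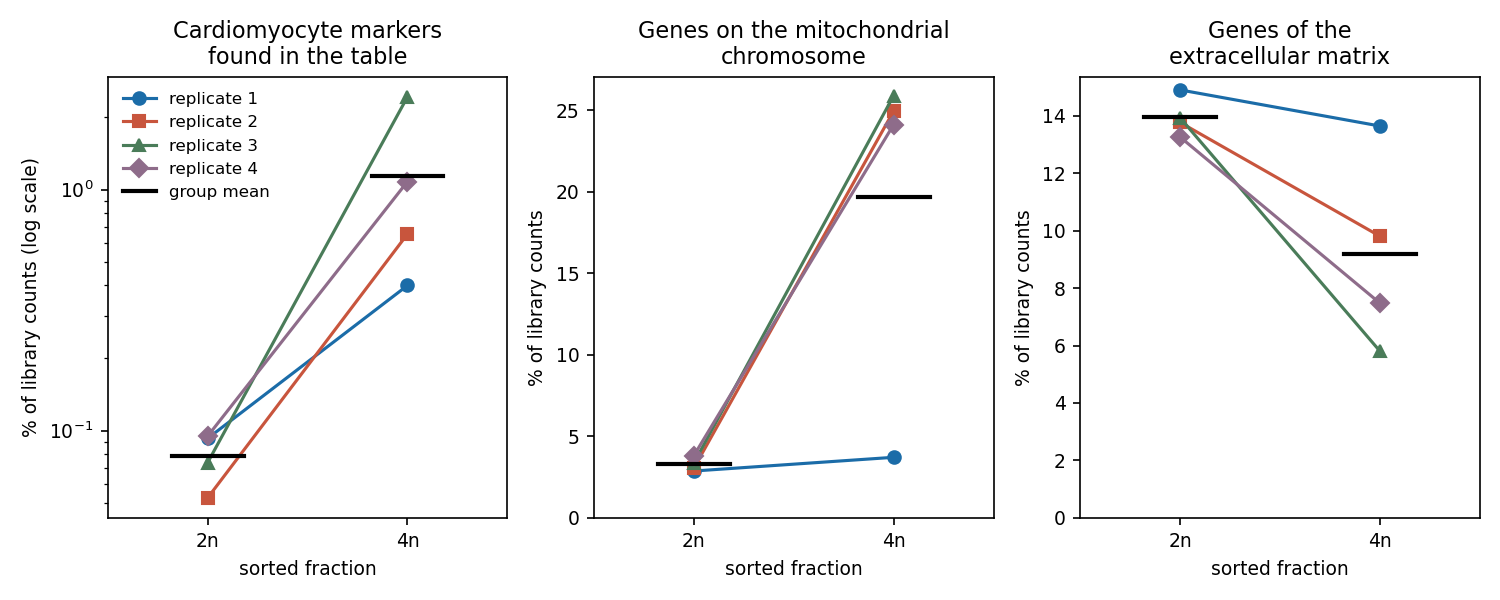
Share of each library's counts, in percent, taken by cardiomyocyte markers (log axis), by genes of the mitochondrial chromosome and by genes of the extracellular matrix, in the 2n and 4n fractions. Points are libraries, lines join libraries with the same replicate number and black bars are group means (n = 4). The mitochondrial share is 3.71% in 4n replicate 1 and between 24.1% and 25.9% in the other 4n libraries.

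**Figure D2:**
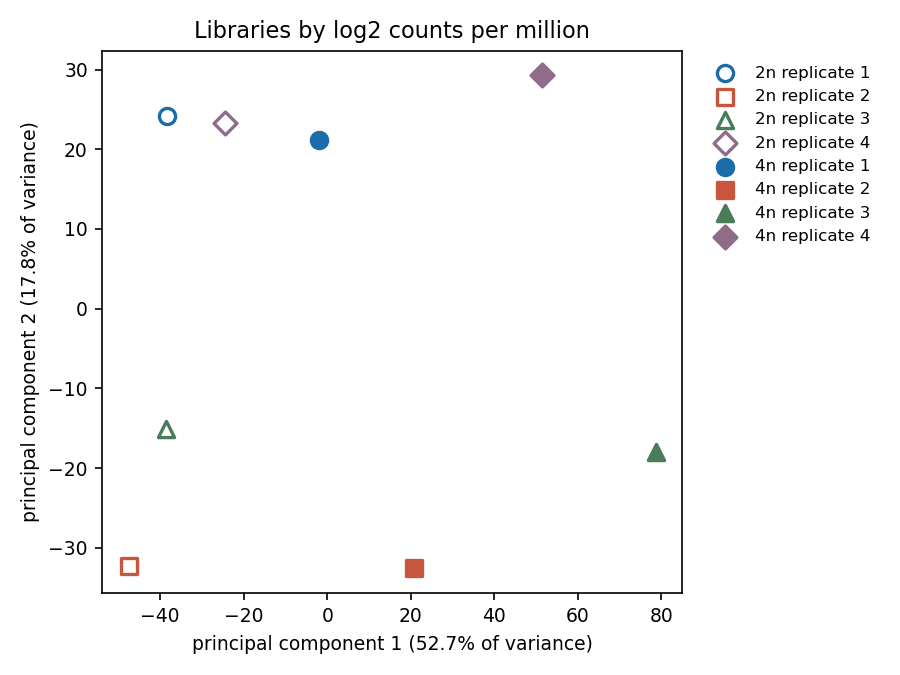
Principal components 1 and 2 of log2 CPM over the genes tested, with the share of variance of each on its axis. Open symbols are 2n and filled symbols 4n libraries, and a symbol's shape and colour give its replicate number. The 2n libraries lie at -24.36 or below on component 1, while the 4n libraries spread from -1.94 to 78.65.

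Across all genes, 347 were higher and 1 was lower in 4n than in 2n in the main fit, which leaves the pairing out (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 12983 genes). The genes that rose did so by a median log2 fold change of 3.33, from 0.63 to 5.62, and each was higher in 4n in 4 of 4 pairs. The largest folds among named genes with a level of at least 5 CPM were in Srpk3, a muscle protein kinase (log2 fold change 4.88 ± 0.79 SE), Inpp5j, an inositol phosphatase (4.87 ± 0.73), and Nppa, the gene of atrial natriuretic peptide (4.87 ± 0.75). Large folds were also found in Glod5 (4.87 ± 0.93), Rxfp1, the relaxin receptor (4.74 ± 0.57), and Unc45b, a chaperone of muscle myosin (4.68 ± 0.76). A4galt (4.64 ± 0.79), Epn3 (4.63 ± 0.96) and Fsd2 (4.63 ± 0.77) followed, and edgeR adjusted p for these genes lay between 0.0252 and 0.0411. Nppa, on chromosome 5 from 164808323 to 164809705 in Rnor_6.0, went from 107 ± 50.8 CPM in 2n to 3138 ± 2645 in 4n (SD, n = 4 each). The gene that fell in the main fit was C7, complement component 7, on chromosome 2 from 54709138 to 54777729. It had 301 ± 41.0 CPM in 2n and 155 ± 40.6 in 4n (SD, n = 4 each), with a log2 fold change of -0.95 ± 0.19 (SE, edgeR adjusted p = 0.0345). With the block it was 1 of 79 genes called lower (edgeR adjusted p = 0.0226).

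With the replicate number as a block, edgeR called 554 genes higher and 79 lower, and 265 of the 347 genes were among the 554. These counts were 0 and 0 without pair 2 or pair 4, with 1962 and 1404 genes higher at an unadjusted p under 0.05, and 1254 and 399 without pair 1. Among the genes closest to passing as lower in 4n without the block were Dzip1, Adamts5, Exoc6b, Setbp1, Igf1, Trps1, Zfp287 and Uggt2, with log2 fold changes between -0.79 and -0.42 and edgeR adjusted p from 0.0567 to 0.0741. Of these, Dzip1, Exoc6b, Setbp1, Igf1, Trps1 and Zfp287 passed with the block, at edgeR adjusted p from 0.0233 to 0.0436. The counts without the block also changed on leaving out single libraries, which lowers the power of the test too. Leaving out 2n replicate 1, 2, 3 or 4, or 4n replicate 4, left 0 genes past the threshold in edgeR, with 1478, 1439, 1304, 1391 and 1336 genes higher at an unadjusted p under 0.05 in that order, and leaving out 4n replicate 1 gave 870 higher and 90 lower. By other tools, DESeq2 called 926 genes higher and 81 lower, and limma-voom called 0 and 0, with 1456 higher and 691 lower at an unadjusted p under 0.05.

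**Figure D3:**
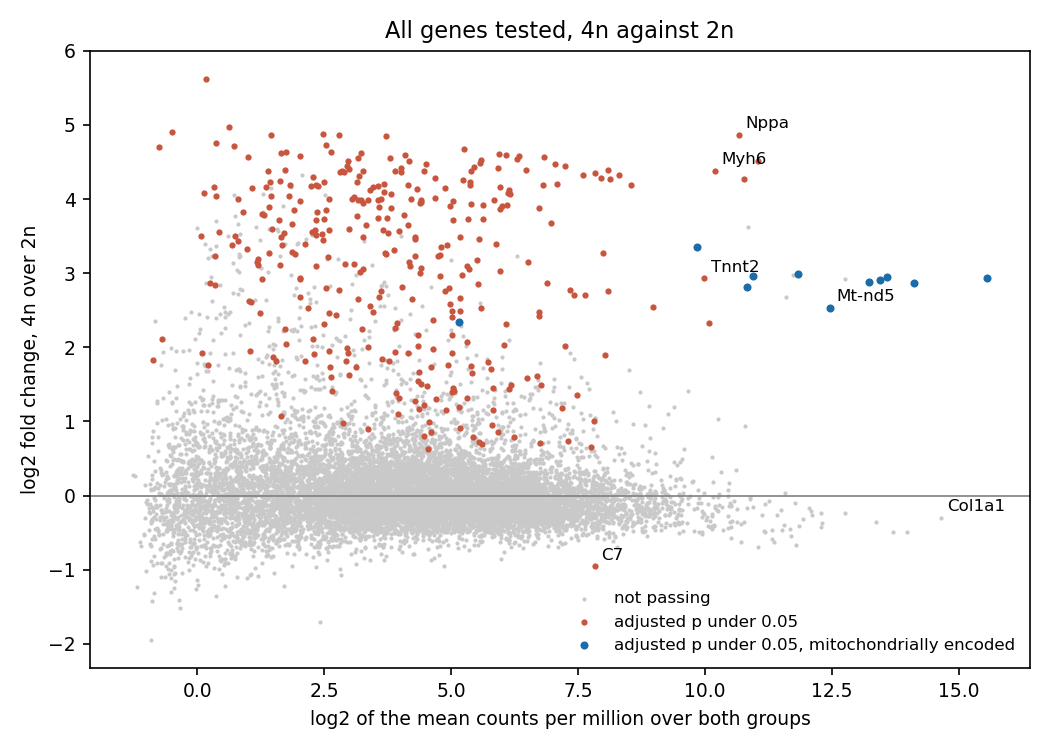
Log2 fold change, 4n over 2n, of each of the 12983 genes tested against the log2 of its mean CPM over both groups. Coloured points pass an adjusted p of 0.05 in edgeR's quasi-likelihood test, with mitochondrially encoded genes in blue. In this fit, which is without the replicate block, the 347 genes that rose lie between 0.63 and 5.62, and C7 alone passes below 0, at -0.95.

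Sarcomere genes, which encode the contractile apparatus, rose together. Of 22 tested, 21 rose and 22 passed when adjusted over the list alone, with a median log2 fold change of 4.24 (camera adjusted p = 3.05e-26 with the preset correlation; adjusted p = 0.378 with an estimated correlation). With the block 17 of the 22 passed in edgeR, and the other 5, Myh6 among them, had edgeR adjusted p from 0.0503 to 0.0664. The median was 3.45 without 4n replicate 3 and 3.58 on FPKM values. Tnnc1, cardiac troponin C, went from 24.9 ± 5.56 to 523 ± 426 CPM, Csrp3, a Z-disc protein, from 14.0 ± 4.48 to 257 ± 190, and Tnni1, slow skeletal troponin I, from 11.3 ± 3.00 to 253 ± 238 (SD, n = 4 each). Their log2 fold changes were 4.39 ± 0.61, 4.20 ± 0.57 and 4.48 ± 0.65 (SE), and that of Mypn, or myopalladin, was 3.55 ± 0.47, all at an edgeR adjusted p of 0.0252. The cardiac myosin heavy chain genes Myh6 and Myh7 rose by 4.39 ± 0.70 and 4.28 ± 0.70, at an edgeR adjusted p of 0.0252 for both. With the block, Myh6 had an edgeR adjusted p of 0.0535 and no longer passed, and Myh7 had 0.0491. These neighbouring genes on chromosome 15 are near-identical in parts, so the split of reads between them is uncertain. Tnnt2, cardiac troponin T, rose by 2.94 ± 0.53 (edgeR adjusted p = 0.0275).

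All 11 cardiomyocyte markers tested rose, and 11 passed when adjusted over the list alone, with a median log2 fold change of 4.36 (camera adjusted p = 1.24e-15; adjusted p = 0.378 with an estimated correlation). With the block 10 of the 11 passed in edgeR. The 11 markers also stand in other lists. Nkx2-5, a transcription factor of the cardiac lineage, rose from 1.53 ± 0.994 to 34.3 ± 26.3 CPM, Tnni3, cardiac troponin I, from 13.2 ± 2.93 to 288 ± 277, and Myl7, the atrial myosin light chain, from 0.672 ± 0.382 to 14.2 ± 9.85 (SD, n = 4 each). Their log2 fold changes were 4.52 ± 0.66, 4.45 ± 0.67 and 4.36 ± 0.63, and that of Actc1 was 4.52 ± 0.67 (SE; edgeR adjusted p = 0.0252 for each). By pair, the median of the list was 2.31, 4.66, 5.64 and 3.65 on the log2 scale for replicates 1 to 4. Without 4n replicate 3 it was 3.52, and on FPKM values 3.59.

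Genes for calcium handling and ion channels also rose: 11 of 21 tested, and 17 adjusted over the list alone, with a median log2 fold change of 2.48 (camera adjusted p = 2.63e-14; adjusted p = 0.378 with an estimated correlation). Hcn4, a pacemaker channel, rose by 4.60 ± 0.72, Casq2, cardiac calsequestrin, by 4.32 ± 0.70, and Pln, phospholamban, by 4.27 ± 0.70 (SE; edgeR adjusted p = 0.0252 for each). Among fetal and stretch-responsive cardiac genes, 8 of 17 rose, and 11 passed when adjusted over the list alone, with a median of 1.76 (camera adjusted p = 1.02e-08; adjusted p = 0.378 with an estimated correlation). These included Nppb, which encodes brain natriuretic peptide, from 18.5 ± 8.03 to 372 ± 265 CPM (SD, n = 4 each; log2 fold change 4.33 ± 0.61 SE), Xirp1 (4.13 ± 0.58) and Acta1, skeletal actin (4.19 ± 0.59), each with an edgeR adjusted p of 0.0252. With the block, 11 genes of the calcium handling list and 8 of the fetal list passed in edgeR. The calcium handling median was 1.30 on FPKM values, and the fetal median 1.17 with the block and without replicate 3. Acta1 shares long stretches of sequence with Actc1, so reads may have been split between the actin genes by the counting.

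The lists of oxidative phosphorylation and fatty acid oxidation were called higher in 4n by camera with the preset correlation alone. They were not called with fry (adjusted p = 0.0763 and 0.0897). All 33 nuclear-encoded genes of oxidative phosphorylation had positive folds, 6 rose, and 33 passed when adjusted over the list alone, with a median of 1.14 (camera adjusted p = 2.73e-18; adjusted p = 0.399 with an estimated correlation). With the block 8 of the 33 passed in edgeR. By pair the median was 0.40, 0.69, 1.78 and 1.17 for replicates 1 to 4, and without 4n replicate 3 it was 0.74. The muscle isoform Cox6a2, a subunit of cytochrome c oxidase, rose by 4.59 ± 0.58 and Cox8b by 4.97 ± 0.70 (SE). The subunits Cox5b and Cox4i1 rose by 1.59 ± 0.32 and 1.00 ± 0.21 (SE), with edgeR adjusted p from 0.0252 to 0.0396 over these genes. Cox8b was near the floor, at 0.0891 ± 0.0284 CPM in 2n and 3.01 ± 2.16 in 4n (SD, n = 4 each). In fatty acid oxidation, 3 of 21 genes rose and 16 passed when adjusted over the list alone, with a median of 0.85 (camera adjusted p = 2.03e-09; adjusted p = 0.414 with an estimated correlation). Without 4n replicate 3 the median was 0.54, or 0.49 with the block and without that pair, and on FPKM values it was 0.48. The genes that rose were Fabp3, the heart fatty acid binding protein (2.70 ± 0.54, edgeR adjusted p = 0.0353), Cd36, a fatty acid transporter (4.01 ± 0.81, edgeR adjusted p = 0.0368), and Cpt1b, the muscle carnitine palmitoyltransferase (2.32 ± 0.51, edgeR adjusted p = 0.0481). With the block 3 of the 21 passed, while Cpt1b had an edgeR adjusted p of 0.0798, and Eci1, an enoyl-CoA isomerase, moved from 0.0703 to 0.0396. Among 18 glycolysis genes, Ldhb, a heart-type lactate dehydrogenase (2.77 ± 0.51, edgeR adjusted p = 0.0285; 0.0548 with the block), and Pgam2, the muscle phosphoglycerate mutase (4.75 ± 1.01, edgeR adjusted p = 0.0431), rose, and 2 passed when adjusted over the list alone. Pgam2 was near the floor, at 0.0807 ± 0.104 CPM in 2n and 2.52 ± 2.72 in 4n (SD, n = 4 each), where replicate 3 stood highest at 6.58. With the block, 1 of the 18 passed. The median of the glycolysis list was 0.32 (camera adjusted p = 0.0179; adjusted p = 0.854 with an estimated correlation and 0.662 with fry), and its call was lost on leaving out 2n replicate 2 or 4n replicate 1, 3 or 4 (camera adjusted p = 0.519, 0.116, 0.0766 and 0.0554). Its median was 0.12 without 2n replicate 2, 0.13 without 4n replicate 3 and 0.06 on FPKM values, but 0.54 without 4n replicate 2. The muscle enolase Eno3 and the muscle phosphofructokinase Pfkm had log2 fold changes of 1.65 and 0.92 and did not pass (edgeR adjusted p = 0.140 and 0.201). Nor did Hk2, a hexokinase, and Pkm, the pyruvate kinase of most tissues, with log2 fold changes of -0.28 and -0.10 (edgeR adjusted p = 0.800 and 0.918).

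Of the 13 mitochondrially encoded genes, 11 rose, and 13 passed when adjusted over the list alone, with a median log2 fold change of 2.91 (camera adjusted p = 5.18e-10; adjusted p = 0.399 with an estimated correlation). With the block, 0 of the 13 passed in edgeR. Mt-nd5, a subunit of complex I, went from 1660 ± 269 to 9631 ± 5067 CPM (SD, n = 4 each; log2 fold change 2.54 ± 0.49 SE, edgeR adjusted p = 0.0332; 0.0667 with the block). Mt-atp6, Mt-nd4 and Mt-nd4l rose by 2.81 ± 0.54, 2.99 ± 0.58 and 2.96 ± 0.58 (SE; edgeR adjusted p from 0.0322 to 0.0337; 0.0663 to 0.0740 with the block). By pair, the median of the list was 0.37, 3.41, 3.27 and 2.87 for replicates 1 to 4, so the pair of replicate 1 stood apart. The median was 2.24 on FPKM values and 2.21 with the block and without replicate 2. Copies of mitochondrial sequence in the nuclear genome can share reads with these genes, which leaves the counts of single genes uncertain.

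**Figure D4:**
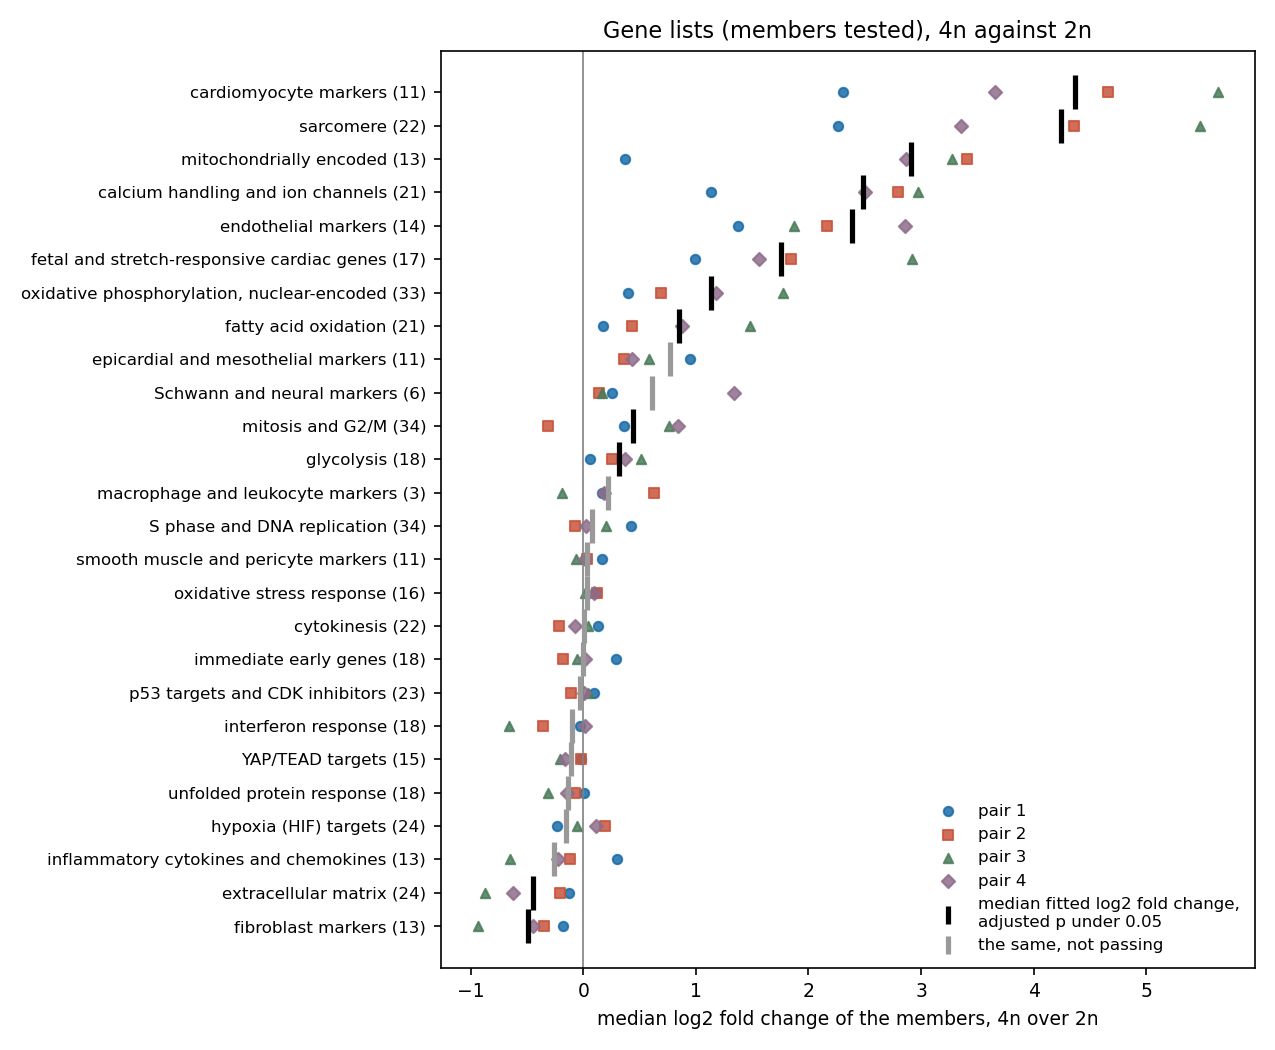
Median log2 fold change, 4n over 2n, of the tested members of each gene list, with the number of members in parentheses. Vertical bars are medians of the fitted values, black where camera with the preset correlation gave an adjusted p under 0.05, and points are the medians within each pair of libraries with the same replicate number. Cardiomyocyte markers (4.36) and sarcomere genes (4.24) lie highest, and fibroblast markers (-0.49) and extracellular matrix (-0.44) lowest.

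The mitosis and G2/M list was called slightly higher in 4n by camera with the preset correlation alone, and no member passed by itself. It was not called with fry (adjusted p = 0.192). All 34 members had positive folds, with a median of 0.44, a fold of 1.36, and 0 of 34 passed in edgeR either over all genes or adjusted over the list alone (camera adjusted p = 4.39e-08; adjusted p = 0.588 with an estimated correlation). In the pair of replicate 2 the median was below 0, at -0.31, against 0.36, 0.76 and 0.84 in the pairs of replicates 1, 3 and 4. The median of the list was 0.26 with the block and without replicate 4, 0.22 with total count scaling and 0.15 on FPKM values. Ccnb1, cyclin B1, came closest, with 24.9 ± 1.92 CPM in 2n and 45.4 ± 12.2 in 4n (SD, n = 4 each; log2 fold change 0.87 ± 0.20 SE, edgeR adjusted p = 0.0570). Aurka, Nusap1 and Ube2c, which act in the spindle or in mitotic exit, had log2 fold changes of 0.89, 0.71 and 0.77 and did not pass (edgeR adjusted p from 0.152 to 0.168). Nor did Mki67, Cdk1, Top2a, Aurkb and the cytokinesis gene Anln, with log2 fold changes of 0.19, 0.45, 0.55, 0.33 and 0.33 (edgeR adjusted p from 0.210 to 0.645). The lists of S phase and of cytokinesis had medians of 0.08 and 0.01 and were not called (camera adjusted p = 0.278 and 0.806). The S phase list was called higher in 4n on leaving out 2n replicate 2 or 4n replicate 4 (camera adjusted p = 0.000269 and 0.0185; adjusted p = 0.614 and 0.862 with an estimated correlation), and with the block on leaving out replicate 2 or 4 (camera adjusted p = 0.00445 and 0.0257; adjusted p = 0.591 and 0.843 with an estimated correlation). Mcm2, part of the replicative helicase, had a log2 fold change of -0.12 ± 0.25 and Cdkn1a, the CDK inhibitor p21, of 0.44 ± 0.44 (SE, edgeR adjusted p = 0.846 and 0.647). With the block these were -0.09 ± 0.14 and 0.35 ± 0.16 (SE, edgeR adjusted p = 0.701 and 0.180). The list of p53 targets and CDK inhibitors was not called (median -0.03, mean 0.07, camera adjusted p = 0.983).

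Extracellular matrix genes and fibroblast markers were called lower in 4n by camera with the preset correlation alone. They were not called with fry (adjusted p = 0.122 and 0.0763). The matrix list had a median of -0.44, with 1 positive fold among 24 genes (camera adjusted p = 1.55e-06; adjusted p = 0.414 with an estimated correlation), and the fibroblast list a median of -0.49 over 13 genes, all negative (camera adjusted p = 6.07e-05; adjusted p = 0.383 with an estimated correlation). Without 4n replicate 3 the matrix median was -0.29 and the fibroblast median -0.37, and on FPKM values they were -0.73 and -0.77. No member of either list passed in edgeR, over all genes or adjusted over the list alone, and with the block 3 fibroblast markers were called lower. Postn, which encodes periostin, stood at 4352 ± 704 CPM in 2n and 2743 ± 503 in 4n (SD, n = 4 each; log2 fold change -0.67 ± 0.19 SE, edgeR adjusted p = 0.106). Fbln1, or fibulin 1, had a log2 fold change of -0.54 ± 0.21 (SE; edgeR adjusted p = 0.233; 0.0421 with the block), and Dpt and Ddr2 had -0.49 and -0.53. Among matrix genes, the fibrillin gene Fbn1 had -0.62 ± 0.19, Col12a1 -0.70 ± 0.25, Col6a1 -0.59 ± 0.22, the protease gene Mmp14 -0.48 ± 0.20 and Col1a1 -0.30 ± 0.25 (SE; edgeR adjusted p from 0.144 to 0.585).

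Endothelial markers were called higher in 4n by camera with the preset correlation alone (camera adjusted p = 0.000478, and 0.588 with an estimated correlation). They were not called with fry (adjusted p = 0.192). The median log2 fold change was 2.39 over 14 genes, with 11 positive and 3 negative folds. The negative folds were in Eng, Flt1 and Tek, the most abundant of these markers in 2n. In edgeR 0 of the 14 passed over all genes, 9 passed when adjusted over the list alone, and 8 passed with the block. Kdr, a receptor of vascular endothelial growth factor, had 2.61 ± 2.00 CPM in 2n and 29.8 ± 29.8 in 4n (SD, n = 4 each; edgeR adjusted p = 0.0600; 0.0303 with the block). Vwf, Emcn and Tie1 had log2 fold changes of 2.83, 2.98 and 2.23 (edgeR adjusted p from 0.0817 to 0.128; 0.0156 to 0.0464 with the block). The list was not called when only genes with a mean of at least 10 CPM were kept (camera adjusted p = 0.126). On FPKM values its median was 0.37, over the 8 markers abundant enough on that scale (camera adjusted p = 0.0397; adjusted p = 0.640 with an estimated correlation). Without the block, leaving out 4n replicate 4 lowered its median from 2.39 to 1.32 (camera adjusted p = 0.00234; adjusted p = 0.508 with an estimated correlation). Lists for the remaining cell types were not called: smooth muscle and pericyte (median 0.04, camera adjusted p = 0.983 with a downward sign), epicardial and mesothelial (0.77, 0.368), Schwann and neural (0.61, 0.368) and macrophage and leukocyte (0.22, 0.837, with 3 of 16 markers abundant enough to test). Of the 6 Schwann and neural markers tested, 1 rose, which was Dbh, the gene of dopamine beta-hydroxylase (log2 fold change 3.71 ± 0.66 SE, edgeR adjusted p = 0.0261), chosen after its value was seen. The macrophage list was called higher in 4n on leaving out 2n replicate 1, 2n replicate 4 or 4n replicate 3 (camera adjusted p = 0.0256, 0.0358 and 2.01e-05; adjusted p = 0.505, 0.541 and 0.146 with an estimated correlation, and 0.00594 with fry for the last), and with the block on leaving out replicate 3 (camera adjusted p = 0.00141; adjusted p = 0.559 with an estimated correlation). The epicardial list was called higher in 4n on FPKM values and, with the block, on leaving out replicate 3 (camera adjusted p = 0.0379 and 0.0440; adjusted p = 0.623 and 0.559 with an estimated correlation). With the block, 4 epicardial markers passed, against 0 without it. No erythroid marker was abundant enough to test.

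Both groups had been hypoxic, and targets of the hypoxia-inducible factors (HIF) were not called as different between them. The median over 24 HIF targets was -0.15 (camera adjusted p = 0.781), and the list was called lower in 4n on leaving out 2n replicate 2 (camera adjusted p = 0.00663; adjusted p = 0.717 with an estimated correlation). Vegfa, the gene of vascular endothelial growth factor A, stood at 711 ± 516 CPM in 2n and 655 ± 386 in 4n (SD, n = 4 each). Its log2 fold change was -0.12 ± 0.56 (SE, edgeR adjusted p = 0.935). With the block it was -0.0014 ± 0.12 (SE, edgeR adjusted p = 0.995). The other stress and signalling lists were not called either. Their medians were -0.11 for YAP/TEAD targets (camera adjusted p = 0.273), -0.13 for the unfolded protein response (0.433), 0.03 for the oxidative stress response (0.781), -0.10 for the interferon response (0.278), -0.26 for inflammatory cytokines and chemokines (0.686) and below 0.01 in size for immediate early genes (0.983). The interferon list was called lower in 4n on leaving out 4n replicate 4 (camera adjusted p = 0.000677; adjusted p = 0.559 with an estimated correlation), and with the block on leaving out replicate 4 (camera adjusted p = 0.0231; adjusted p = 0.675 with an estimated correlation). With the block, edgeR called 1 HIF target lower, and 1 gene of the p53 list, 2 of the unfolded protein response and 1 of the oxidative stress response higher, against 0 in each list without it.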

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

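The comparisons in this part were chosen after the results were seen. They draw in part on fits planned in advance, namely other scalings, the block and leaving out libraries or pairs. The scaling without the mitochondrial genes was not among those planned. Within each group of 4 libraries, 220 values (list means, shares of counts and named genes) were searched for a library far from the other 3, a search in which chance gives about 1 in 20, and 16 stood out. Of these, 6 belong to 4n replicate 1. Its share of mitochondrial counts was 3.71%, against 24.1% for the nearest library of the group, its mean over the mitochondrially encoded list was 10.04 log2 CPM against 13.00, and its share of counts in the 10 most abundant genes was 12.4% against 24.5%. In the same library Mt-nd5, Mt-nd4 and Mt-nd4l were lowest, at 11.01, 9.92 and 9.06 log2 CPM. In 4n replicate 4 the endothelial list was highest, at 5.38 log2 CPM against 3.26 for the next library, as was Emcn at 4.15. In 4n replicate 2, Ube2c was lowest, at 4.37. In 2n replicate 2 the glycolysis list was lowest, at 6.48 against 7.61, as was Eno3 at 2.13. In 2n replicate 4 the interferon list was highest, at 2.76 against 1.52, as were Cdkn1a at 7.30 and Mypn at 0.43, and Igf1 was lowest at 5.05. In 2n replicate 1, Dpt was lowest, at 5.62.

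The first pattern, the rise of cardiac genes in 4n, is not an effect of scaling, since the median log2 fold change of the sarcomere list was at least 3.92 under 5 scalings. A larger share of cardiomyocytes in the 4n libraries stays possible. In 2n the cardiomyocyte markers took 0.0786% of the counts, against 14.0% for genes of the extracellular matrix. The contrast may therefore be in part one between cell types, and not one between 2n and 4n cardiomyocytes. For the 29 called cardiac genes outside the markers, the excess of 4n over 2n per unit of marker excess varied between pairs by a median factor of 1.62. It was 1.64 for the markers among themselves and 10.4 for a gene with an equal excess in all pairs. The called genes were chosen as higher in 4n in the same data, so genes that break the proportion could be left out beforehand. The factor therefore cannot decide the question. Cardiac genes not called were not compared, and 1 of 21 calcium handling genes and 2 of 17 fetal genes had negative folds. The factor between pairs was at most 3.60, the highest of the markers, for 284 of the 336 called genes outside the markers. The fibroblast list was below 0 in every pair, with medians of -0.18, -0.35, -0.94 and -0.44. A larger share of cardiomyocytes alone would lower the other cell types too, but their lists did not fall alike. Smooth muscle and pericyte medians were 0.16, 0.03, -0.07 and 0.02, and macrophage medians 0.17, 0.62, -0.19 and 0.19. Epicardial, Schwann and endothelial medians were above 0 in every pair. Of the lists that did not fall, only the endothelial list was called. The macrophage and Schwann medians rest on 3 and 6 tested genes, so they are weak evidence here. A change of a whole cardiac programme within cells of 4n DNA content would give the same proportions. Like ploidy itself, it stays open and untested, because a library averages over its cells. Pairs of 2n cells joined at random and sorted as 4n would keep the marker share of 2n. That share was at most 0.0949% in 2n and at least 0.400% in 4n, which argues against such pairs as the only source. Pairs made mostly of cardiomyocytes stay open and were not tested. Of all 35 splits of the 8 libraries only the real one, with 348 genes, gave as many (1 of 35 as large, highest other 7), but since the numbers pair the samples the comparison is with the 8 splits that part all 4 pairs, the others parting 0 or 2, and these are too few for a share under 0.05 (highest other 0); the 8 are also too few for the 12 lists called with camera's preset correlation (4 of 8 as large, highest other 13), and of all 35 splits 21 gave 12 or more lists and the highest other 20, which points to differences between libraries that genes of a list share.

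The next pattern is the rise of mitochondrially encoded transcripts in 4n replicates 2, 3 and 4. A larger share of cardiomyocytes is argued against as its only source, since the summed mitochondrial excess per unit of marker excess differed 13.8-fold between pairs, from 2.61 in replicate 1 to 36.1 in replicate 2, while the excess of nuclear oxidative phosphorylation genes stayed between 0.275 and 0.336. A difference between experiments that acted alike on the cells of both libraries of a replicate is argued against too. The 2n libraries differed 1.33-fold in mitochondrial share and the 4n libraries 6.98-fold. A difference between experiments confined to cardiomyocytes stays open. It would barely show in 2n, where cardiomyocyte markers took 0.0786% of the counts. Scaling is argued against by a median log2 fold change of at least 2.59 over the scalings. Handling of the 4n fraction that differed between the experiments, damage to the sorted cells and a change in mitochondrial RNA in 4n cells stay open and were not tested.

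The last pattern is the rise of endothelial markers in 4n. A source in 4n replicate 4 alone is argued against, since the median log2 fold change was 1.37, 2.16 and 1.87 in pairs 1 to 3 and 1.90 with the replicate block and without replicate 4 (camera adjusted p = 4.58e-05; adjusted p = 0.675 with an estimated correlation), although without the block leaving out 4n replicate 4 lowered it from 2.39 to 1.32 (camera adjusted p = 0.00234; adjusted p = 0.508 with an estimated correlation). A larger share of cardiomyocytes alone would lower endothelial and fibroblast markers alike, but the endothelial median exceeded the fibroblast median by at least 1.55 on the log2 scale in each pair. The 3 most abundant markers in 2n, Eng, Flt1 and Tek, had log2 fold changes of -0.30, -0.20 and -0.21 and did not pass, and the summed excess of the list in 4n over 2n was 19.8, -38.4, -130 and 438 CPM in pairs 1 to 4. More endothelial cells in the 4n gate, which selects on DNA content and not on cell type, may be a source, as may endothelial cells sorted in pairs, and neither was tested.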

How the results depend on the processing

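Without the block 347 genes were higher and 1 was lower. With the replicate block the counts were 554 and 79. The block changed the calls of 20 named genes, 7 of which no longer passed and 13 of which passed newly. It changed no list call under camera's preset correlation, but the 4 lists called with fry no longer passed (fry adjusted p from 0.0794 to 0.0899). Higher and lower counts were 926 and 81 with DESeq2, 1331 and 575 with DESeq2 and the replicate block, 0 and 0 with limma-voom (smallest adjusted p 0.0620), and 184 and 12 on FPKM values. A mean of at least 10 CPM gave 174 higher, a count that goes with fewer genes tested (8717). Lower genes numbered 3 with upper-quartile scaling, 12 with total count scaling, 0 at 2-fold or more and 2 without the mitochondrial genes. Leaving out single libraries or pairs gave from 0 to 1254 higher and from 0 to 399 lower genes. The counts were 0 without any of the 2n libraries or without 4n replicate 4, and with the block also without pair 2 or pair 4, where 1962 and 1404 genes were higher at an unadjusted p under 0.05 in edgeR. They were 870 and 90 without 4n replicate 1, and with the block 1254 and 399 without pair 1 and 558 and 50 without pair 3. Lists higher and lower in 4n numbered 10 and 2, and 0 and 0 with an estimated correlation and 4 and 0 with fry. Except where an alternative's construction shows it, the cause was not tested. No named gene or list changed direction among calls. Total count scaling shifted the median of all genes to -0.25 on the log2 scale, against -0.01 with TMM, and the matrix and fibroblast medians of -0.65 and -0.72 are to be read relative to it, as is the glycolysis median of 0.09. On FPKM values, scaled by total counts with 1 added before the log, the median of all genes was -0.22, and list medians on that scale are to be read relative to it. Under every scaling the medians of the called lists kept their sign, though the mitochondrially encoded list has no value where its genes were left out. Without the block 37% of simulated 2-fold changes were recovered, so smaller changes can go undetected. The simulation left out the wider spread of the 4n libraries, so recovery in the data may be lower.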

Other observations

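Both libraries of replicate 2 had the lowest means over HIF targets, and both of replicate 4 the highest over inflammatory cytokines and chemokines. For HIF targets the means of replicate 2 were 5.45 log2 CPM in 2n and 5.68 in 4n, against values from 6.79 to 7.72 in the other 6 libraries. Bnip3, a mitophagy receptor induced by HIF, stood at 21.2 and 30.6 CPM in 2n and 4n replicate 2, against 167 to 278 CPM elsewhere, and Ndrg1 at 9.50 and 11.6 against 44.7 to 248. Egln3, a HIF target, stood at 132, 4.95, 48.1 and 96.6 CPM in 2n replicates 1 to 4 and at 142, 38.2, 354 and 214 CPM in 4n. For inflammatory genes the means of replicate 4 were 6.65 log2 CPM in 2n and 6.49 in 4n, against 3.96 to 4.91 in the other libraries. There Il6, an inflammatory cytokine, stood at 19.9 and 26.9 CPM, against 0.644 to 2.20 elsewhere. Ccl2, a chemokine for monocytes, stood at 647 and 522 CPM against 59.1 to 190. These genes were picked after their values were seen, and no test was run, as the labels give no group to the experiments.

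A pair of macrophage markers, picked after their values were seen, were near the floor in 2n. Lyz2, or lysozyme, stood between 0.159 and 0.521 CPM in the 2n libraries, at 4.24, 3.79 and 3.87 CPM in 4n replicates 1, 2 and 4, and at 0.286 CPM in 4n replicate 3. Csf1r, the receptor of a macrophage growth factor, stood at 0.189 CPM or less in 2n, at 1.40, 1.34 and 0.657 CPM in 4n replicates 1, 2 and 4, and at 0 in 4n replicate 3. Both were too low to be tested. Of the 3 macrophage markers tested, Cd14 stood between 3.13 and 5.98 CPM in 2n and between 2.38 and 5.96 in 4n, and it did not pass, nor did Mrc1 and Cd68 (log2 fold changes -0.17, 0.22 and 1.26, edgeR adjusted p = 0.824, 0.848 and 0.404). With no filter on low counts, camera with the preset correlation called the macrophage list higher in 4n (adjusted p = 2.97e-05; adjusted p = 0.320 with an estimated correlation and 0.113 with fry).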
